A study of Drosophila melanogaster with 6 samples.

How the data were processed

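The series holds 6 Affymetrix Drosophila arrays, 1 per sample. Per the labels, embryos aged at 25 C were sorted with a COPAS instrument, RNA was isolated with TRIzol and cleaned on RNeasy columns, and biotin-labelled RNA was made with a 3′ IVT kit. Wild type samples were described as matched in age to the samples with the transgene. Per the submitters' processing notes, RMA and Partek were used, without versions, order or filters. The deposited values were taken as log2 RMA values because they run from 2.90 to 14.6 with nearly equal means per array (6.36 to 6.37), and a log2 scale is what RMA gives. No detection calls were used.

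The value table has 18952 probe sets. The 183 Affymetrix controls were kept out of the tests and described apart, leaving 18769. The 70 among them with Tag, TrpnX or protein accession names were taken to have no fly target and to show background, a choice made after the data were seen. The platform annotation lists 14049 probe sets, of which 13647 are paired with 1 gene and 402 with several. Of the tested probe sets 4720 have no gene listed and are unnamed here. Entrez numbers of 13544 of the 13647 were found in the gene table of the Release 6 assembly, which served for symbols and for the order of genes along chromosomes. No gene was named from a probe set with several genes. Each of 11983 genes was represented by its probe set with the highest mean over all 6 arrays, a choice that matters for 1094 genes with more than 1.

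Sage overexpression was compared with wild type by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values, two-sided tests and Benjamini-Hochberg adjustment over all genes or probe sets at a threshold of 0.05. Fold changes are differences of mean log2 values, Sage overexpression minus wild type. Before the data were examined, 45 gene lists were fixed, along with the test, the alternatives and the rule for named genes. The 44 lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Sage was left out of every list. Counts cover measured genes only, and several lists were measured in part. Measured were 6 of 17 listed heat shock genes, 6 of 12 gland regulators, 14 of 24 cell cycle genes and 21 of 27 muscle genes. Other settings were camera with an estimated correlation, fry, median centring, quantile normalization, leaving out probe sets with means below the median, eBayes with trend and robust settings, array weights, the replicate block, an adjusted p of 0.01, treat with a minimum log2 fold of 0.58, the mean of a gene's probe sets and leaving out each array in turn. One more, without replicate number 2 in both groups, was added after the data were seen.

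The rule for named genes always takes sage, fkh, CrebA, sens, PH4alphaSG1, PH4alphaSG2, pip and w. It adds the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, and for each list described up to 4 members past the threshold by size, or the member with the smallest p. CycE, Papst2, Npc2c, Npc2h, RFeSP, CG42335 and the yellow and cytochrome P450 genes of the family test were named after their values were seen.

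The labels give both groups replicate numbers 1 to 3 without saying what they share. Across tested probe sets, deviations from the group mean correlated at 0.39, 0.67 and 0.33 between samples of the same number. Against these stood 0.43 for wild type 3 with Sage 1, 0.26 for wild type 1 with Sage 3, and -0.38 to -0.57 for the 4 pairs that join number 2 to another. Deviations cancel out within a group by construction, so the negative values follow in part from the 0.67. The values set number 2 apart and do not settle how 1 and 3 pair, and the replicate block takes the numbers as pairs. The second principal component (32.4% of the variance, after 54.1% for the first) separated the samples numbered 2 from the others. The planned fit has no block, and values with the replicate block stand beside a named gene or list where they change its call; member counts of other lists come from the planned fit.

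The procedure was tested on simulated data for the comparison of Sage overexpression with wild type on 18769 probe sets with 3 arrays per group. Of 50 probe sets changed by each of 0.5, 1, 2 and 4 on the log2 scale, 16%, 76%, 88% and 98% were recovered, and 8 of 147 calls were of unchanged ones. In a list simulation 1 of 44 lists was called, the one that had been shifted. The simulated noise was independent between probe sets, whereas the estimated inter-gene correlation was 0.15 in the Cpr and 0.73 in the Tweedle cuticle families. The simulation therefore cannot show how often camera calls lists whose genes vary together. Gene families were compared by symbol stem with Fisher's exact test, and neighbouring genes by 10000 random placements. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.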

Results

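RNA from whole Drosophila embryos of stages 11 to 16 was measured on 6 Affymetrix arrays, 3 from wild type embryos of the Oregon R strain and 3 from embryos in which a UAS-Sage transgene was driven by tub-Gal4, with Oregon R given as the genetic background of both groups. Sage is a basic helix-loop-helix transcription factor of the embryonic salivary gland, and tub-Gal4 is a driver active in most cells. The comparison of Sage overexpression with wild type asks which genes respond when the factor is made outside the gland. The arrays had median log2 values between 5.44 and 5.52. Pearson correlations across probe sets lay between 0.975 and 0.994 among the wild type arrays, between 0.989 and 0.996 among the Sage arrays, and between 0.960 and 0.983 across the groups. The number of arrays limits the precision. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples.

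Sage RNA was 23.1-fold higher in the Sage embryos, with a log2 value of 7.72 ± 0.34 (SD, n = 3) in wild type and 12.25 ± 0.07 in Sage overexpression. Its log2 fold change of 4.53 (SE 0.18) had a limma adjusted p of 5.9e-05, and every Sage array lay above every wild type array. The labels do not say whether the transgene carries the probe set's target, so RNA of the transgene and of the endogenous gene cannot be separated. The response around it was broad and contained a group of very large rises: among 11983 genes, 523 rose and 446 fell at an adjusted p under 0.05. At least 2-fold changes numbered 240 rises and 141 falls, at least 4-fold changes 61 rises and 14 falls, and at least 16-fold changes 12 rises and 0 falls. Of the 61 genes that rose at least 4-fold, 46 were in the lower 50% of wild type means, and 56 passed in each fit that left out 1 array. Groups did not overlap for 3811 genes, or 31.8%, where chance gives 10%, and these included all 969 changed genes. The 70 control probe sets taken here to have no fly target had group means from 3.23 to 5.35. The wild type means of 149 raised genes, among them 27 of the 61, and the Sage means of 67 lowered genes lay no higher than 5.35, so their folds and ranks are not exact. At the level of probe sets, 608 rose and 541 fell of 18769 tested. The number of changed genes varied when 1 array was left out. It was 1638 without wild type array 2, and 366, 320 and 275 without Sage array 1, 2 or 3. The balance moved too, with 261 rises and 105 falls without Sage array 1, 224 and 96 without Sage array 2, and 199 and 76 without Sage array 3. Without wild type array 1 there were 310 rises and 354 falls. With the replicate block, 1767 genes changed, 881 up and 886 down, and 962 of the 969 were among them. Without both arrays numbered 2, a fit added after the data were seen, 1312 genes changed.

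The control RNAs on the arrays also differed between the groups. The polyA spike-ins, bacterial transcripts added to the RNA before labelling, had lower means on the Sage arrays for all 24 probe sets, with a median log2 difference of -1.65, while the hybridisation controls added after labelling had a median difference of 0.08. The dap spike-in read 9.07 ± 0.54 in wild type and 6.82 ± 0.24 in Sage overexpression. The lys spike-in read 6.41 in wild type and 4.90 in Sage overexpression, the latter within the range of the control probe sets without a fly target. Some spike-in differences, and so their median, may therefore understate the fall. The probe sets at the 5′ ends of actin, GAPDH and eIF-4a had log2 differences of -1.38, -1.21 and -1.21, against -0.09, -0.38 and -0.39 at their 3′ ends. The 3′ minus 5′ gap was therefore larger in the Sage samples by 1.29 for actin, 0.83 for GAPDH and 0.82 for eIF-4a. In each of these 3 transcripts the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Group and any batch of labelling or RNA quality cannot be told apart in this design.

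**Figure D1:**
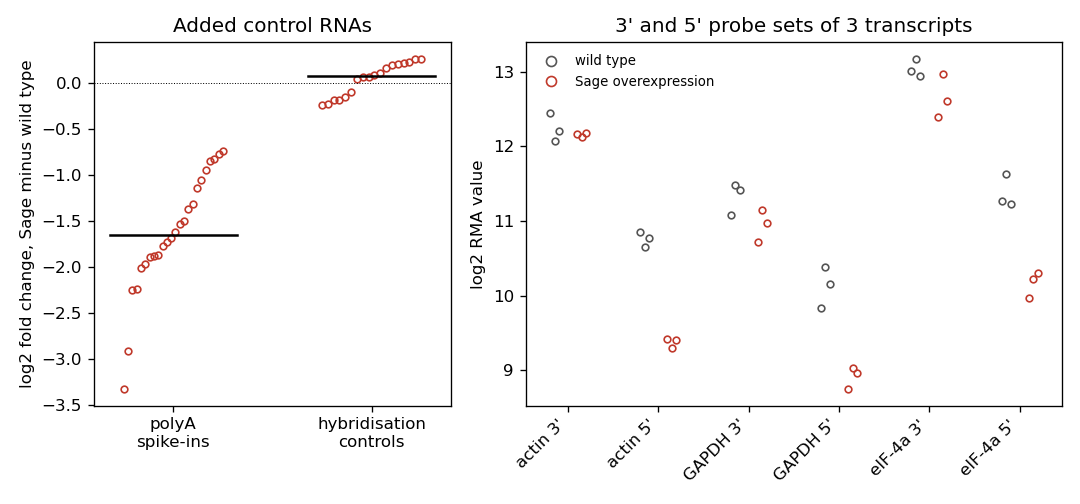
Left, log2 fold change (Sage overexpression minus wild type) of each polyA spike-in and hybridisation control probe set, with medians of -1.65 and 0.08 as lines. Some polyA spike-in probe sets read within the background range on the Sage arrays, so their falls may be understated. Right, log2 RMA values of the 3 wild type (grey) and 3 Sage (red) arrays at the 3′ and 5′ probe sets of actin, GAPDH and eIF-4a, where the 5′ values of the Sage arrays lie below those of wild type.

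Salivary gland genes were among those that rose. The products list, which holds genes for the secretory output of the embryonic gland, had 3 of 10 measured members raised and 0 lowered, both over all genes and adjusted over the list alone. PH4alphaSG1 and PH4alphaSG2, prolyl 4-hydroxylase subunits of the gland, rose 2.82-fold (adjusted p 0.0076) and 2.73-fold (log2 1.45, SE 0.31, adjusted p 0.037). Papss, which makes the sulphate donor for sulphotransferases, rose 1.98-fold (adjusted p 0.0098). As a list the products were shifted upward with a median log2 fold change of 0.41 (camera adjusted p 0.012), a call that is lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation). PH4alphaSG2 missed the threshold when any array but wild type array 2 was left out (adjusted p up to 0.139), and Papss missed it without Sage array 3 (adjusted p 0.057). The list had 5 raised members without wild type array 2, 1 without Sage array 3, and 2 without any other array. For pip, a sulphotransferase gene with many transcripts, the brightest probe set had a log2 fold change of 0.35 (adjusted p 0.38). Of its 10 probe sets 7 had positive values, and 1 passed, with a log2 fold change of 1.29. With the replicate block, probe sets with log2 fold changes of 0.649 and 0.654 passed too (limma adjusted p 0.027 and 0.036). The brightest did not (adjusted p 0.16).

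Regulators of the gland gave a mixed picture. Senseless (sens), a zinc-finger factor that protects gland cells from death and specifies sensory organ precursors, rose 3.85-fold from 6.36 ± 0.23 to 8.30 ± 0.11 (adjusted p 9.1e-04). Fork head (fkh), the FoxA factor of the gland, read 8.15 ± 0.24 in wild type and 8.18 ± 0.15 in Sage overexpression, a log2 difference of 0.03 (SE 0.15, adjusted p 0.94). Of 6 measured regulators 1 rose and 0 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p 0.34). CrebA and w were not analysed here, because no probe set was paired with either gene alone. Among 11 larval glue genes, whose proteins fix the pupa to its substrate, 2 rose and 0 fell, also adjusted over the list alone. Eig71Ee rose from 5.08 ± 0.09 to 10.20 ± 0.32 (adjusted p 2.4e-05) and Sgs4 from 4.51 ± 0.07 to 7.75 ± 0.48 (adjusted p 9.1e-04), both from the range of the controls, while the list median was 0.05 and camera gave an adjusted p of 0.11. The list-wise test fry called the glue list (adjusted p 0.013). Of 9 prolyl 4-hydroxylases 2 rose, PH4alphaSG1 and PH4alphaSG2, 3 when adjusted over the list alone, with a camera adjusted p of 0.36. None of 37 secretory pathway genes passed limma's threshold over all genes or over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, a median of 0.19 and a camera adjusted p of 0.15. With the replicate block 1 of them rose, and without wild type array 2, 5 rose and 1 fell. The list passed in the fits without wild type array 2 (adjusted p 0.0058) and without both arrays numbered 2 (adjusted p 0.021). Of 15 genes for ER chaperones and the unfolded protein response 0 rose and 1 fell, the ER stress sensor Ire1, 1.85-fold, also adjusted over the list alone (camera adjusted p 0.79 for the list). Ire1 missed the threshold without any one of the Sage arrays (adjusted p up to 0.057).

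**Figure D2:**
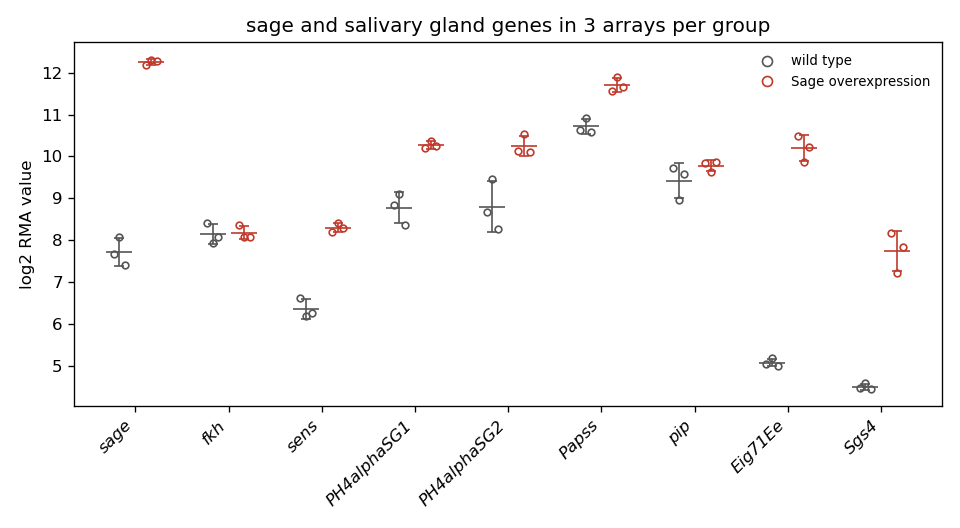
Log2 RMA values of sage and salivary gland genes, with each of the 3 wild type (grey) and 3 Sage (red) arrays as a circle and mean ± SD as bars. Sage rose from 7.72 to 12.25, and Eig71Ee and Sgs4 rose from wild type means of 5.08 and 4.51, while fkh stayed within the spread between arrays.

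Of the 12 largest rises 9 started from wild type means in the range of the control probe sets without a fly target, so their folds are not given and their order is not exact. CG14852 rose from 4.43 ± 0.06 to 10.80 ± 0.10 (adjusted p 2.1e-06). CG14851, Jhbp14, a member of the juvenile hormone binding protein family, CG10853 and CAH5, a carbonic anhydrase, reached 10.28, 10.46, 10.89 and 10.07. Eig71Ee, CG7443, CG17134 and CG13135 reached 10.20, 9.0, 8.98 and 9.37. The 3 that started above that range were CG11300, which rose 73.5-fold, sage, 23.1-fold, and CG9702, 17.6-fold. Their limma adjusted p-values lay between 2.1e-06 and 5.9e-05, and all 12 passed in each fit that left out 1 array. The unnamed probe sets 1631224_at and 1641474_s_at rose from the same range, from 4.35 ± 0.19 to 11.48 ± 0.14 (adjusted p 4.4e-06) and from 4.41 to 8.94.

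The 12 largest falls were smaller, and 7 of them ended in the range of the controls on the Sage arrays, so their folds are not given. Jon44E, a Jonah-family serine protease, fell from 7.94 to 4.83 (adjusted p 0.0027), and the cytochrome P450 gene Cyp6a8 from 7.76 to 4.98. CG18088, CG4404 and CG8100 fell from 7.98, 6.91 and 7.48 to 5.31, 4.45 and 5.31. The early cell cycle gene plu fell from 7.48 to 5.30, and lncRNA:CR32368 from 6.04 to 3.89. The 5 that ended above that range were the cytochrome P450 gene Cyp6a13 (5.30-fold), CG7763 (5.13-fold), the transporter gene MFS1 (5.02-fold), the sodium channel gene rpk (4.63-fold) and the securin gene pim (4.38-fold). CG4404, rpk and plu missed the threshold without wild type array 3 and without any Sage array (adjusted p up to 0.15, 0.132 and 0.153), and pim without any Sage array (adjusted p up to 0.091). In wild type CG4404, rpk, plu and pim had SDs of 1.14, 0.80, 0.99 and 0.75. Their wild type values climbed from array 1 through 2 to 3, for plu from 6.44 through 7.59 to 8.40. The size of these falls therefore depends on the wild type arrays used. Other genes in the 12 passed in each fit that left out 1 array. The unnamed probe set 1632993_at fell from 7.64 to 4.47, within the range of the controls, and 1632841_x_at had a log2 fold change of -3.16.

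**Figure D3:**
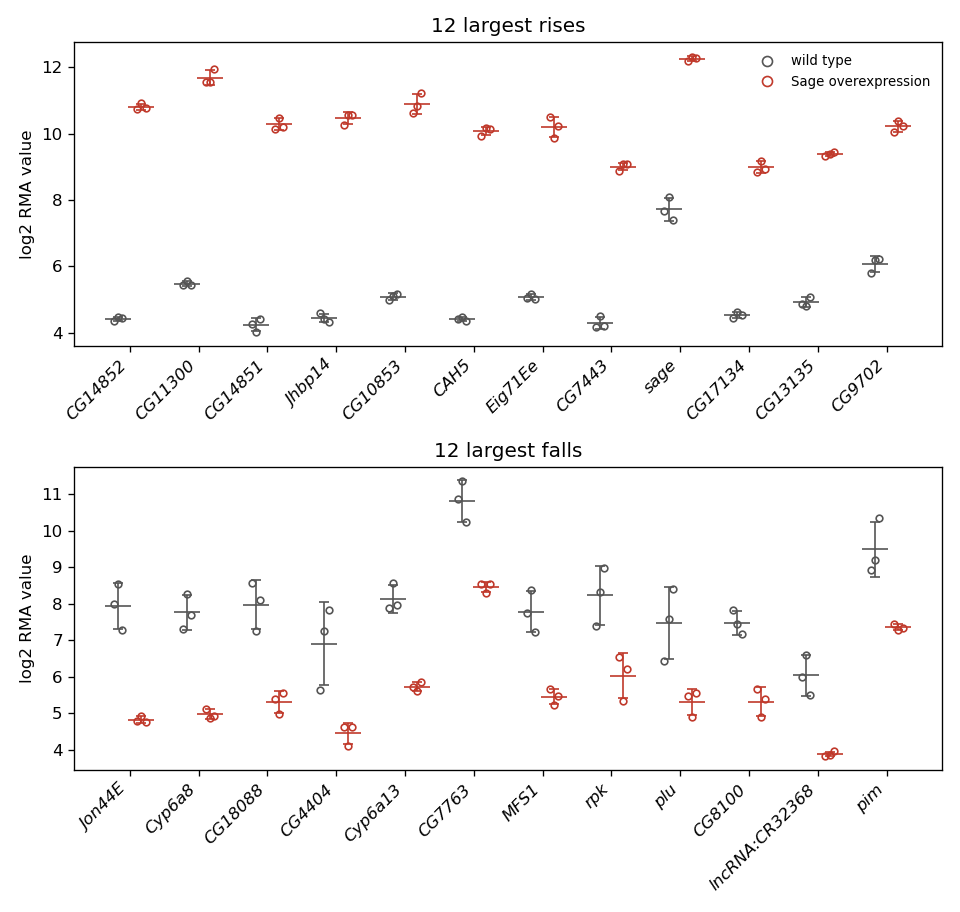
Log2 RMA values of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom), with each of the 3 wild type (grey) and 3 Sage (red) arrays as a circle and mean ± SD as bars. CG14852 rose from 4.43 to 10.80, and Jon44E fell from 7.94 to 4.83.

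Cuticle protein genes were higher in the Sage embryos. Of 66 Cpr genes, which encode chitin-binding cuticle proteins, 7 rose and 0 fell, 18 rose when adjusted over the list alone, and 59 had positive log2 fold changes. Cpr67Fb rose 4.42-fold, Cpr66D 4.22-fold, Cpr65Eb 2.69-fold, and Cpr76Bc from 4.73, within the range of the controls, to 5.99. The median Cpr change was 0.44, with a camera adjusted p of 5.9e-08 (adjusted p = 0.781 with an estimated correlation). Of 24 Tweedle genes, another cuticle family, 2 rose and 0 fell, 3 when adjusted over the list alone. TwdlT rose 6.21-fold from 9.94 to 12.57 (adjusted p 0.0063) and TwdlX 1.87-fold, and the family median was 0.81 (camera adjusted p 2.5e-04; adjusted p = 0.781 with an estimated correlation). The number of Cpr genes past the threshold changed when 1 array was left out. It was 12 without wild type array 2, 3 without wild type array 1 or Sage array 1, 2 without Sage array 2 and 1 without Sage array 3. Such fits also have fewer arrays to estimate the spread, so a lower count need not mark the array left out. TwdlT passed in each of these fits, and TwdlX missed the threshold without wild type array 1 or any Sage array (adjusted p up to 0.147). With the replicate block 17 Cpr and 6 Tweedle genes rose, and 1 Cpr gene fell. The epidermis and cuticle formation list had 1 of 29 members raised, also adjusted over the list alone, Edg91, 2.38-fold, and did not pass (camera adjusted p 0.10), but passed with the replicate block (adjusted p 0.043). Among 27 chitin metabolism genes, the chitinase genes Cht9 and Cht4 rose 6.13-fold and from 5.25, within the range of the controls, to 6.04, with no call for the list (camera adjusted p 0.15), and adjusted over the list alone 3 rose and 1 fell. Edg91 missed the threshold without Sage array 2 (adjusted p 0.052) and Cht4 without Sage array 2 or 3 (adjusted p 0.05025 and 0.067). None of the 24 Osi genes passed in limma over all genes or over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p 0.15). With the replicate block 2 Osi genes rose and 1 fell, and 2 rose without wild type array 2.

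Cell cycle genes were lower. All 14 measured members had negative log2 fold changes, with a median of -0.40, and 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p 5.6e-04; adjusted p = 0.781 with an estimated correlation). Cyclin B (CycB) was 2.47-fold higher in wild type, the APC activator fzy 2.18-fold, and the chromosomal passenger genes Incenp and aurB 1.96-fold and 1.78-fold. The fifth was CycE, 1.6-fold, named after its values were seen. The germ line and maternal list shifted downward with 3 of 19 members lowered and 0 raised, 5 when adjusted over the list alone, namely plu, CycB and the piRNA factor gene aub (1.59-fold) over all genes. Its camera adjusted p was 0.012 (adjusted p = 0.781 with an estimated correlation). CycB and plu are regulators of division, and CycB also stands in the cell cycle list. Without Sage array 1, 2 or 3 no cell cycle gene passed, and 3 passed without wild type array 3, although the list kept its call in each of these fits. Germ line and maternal genes past the threshold numbered 1, 1 and 0 without Sage array 1, 2 and 3, and that list kept its call too, but lost it with array weights (adjusted p 0.059). The 5′ control probe sets named above were lower on the same arrays. Among all 5′ control probe sets the largest fall was a log2 change of -1.48. Of the 446 lowered genes 397 fell by less than that, among them the 5 cell cycle genes. Among the 3′ control probe sets the largest fall was a log2 change of -0.59, smaller than the fall of each of these 5 genes. Positions of probe sets along their transcripts were not used, so neither value shows how far labelling accounts for these falls.

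The Enhancer of split and Notch response list also shifted downward, with 2 of 13 members lowered and 0 raised, 4 when adjusted over the list alone, and a median of -0.46 (camera adjusted p 0.023; adjusted p = 0.781 with an estimated correlation). These were Tom, 2.03-fold, and E(spl)m2-BFM, 1.51-fold, both Bearded-family inhibitors of Notch signalling. The list missed the threshold without wild type array 1 (adjusted p 0.206), without Sage array 2 (adjusted p 0.069), without Sage array 3 (adjusted p 0.0502) and with dim probe sets left out (adjusted p 0.059). Tom missed it without wild type array 1 or any Sage array (adjusted p up to 0.161), and E(spl)m2-BFM without any array but wild type array 2 (adjusted p up to 0.163). Mitochondrial ribosomal protein genes shifted downward with a median of -0.20 (camera adjusted p 0.012; adjusted p = 0.808 with an estimated correlation). Of the 69 genes 1 rose, mRpL48, 2.0-fold, and 2 fell, mRpS5 and mRpS11, also adjusted over the list alone, although neither fall passed without any one of the Sage arrays (adjusted p up to 0.128). That call ended without wild type array 2 (adjusted p 0.69) or Sage array 1 (adjusted p 0.095), without both arrays numbered 2 (adjusted p 0.20), with dim probe sets left out and with array weights.

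**Figure D4:**
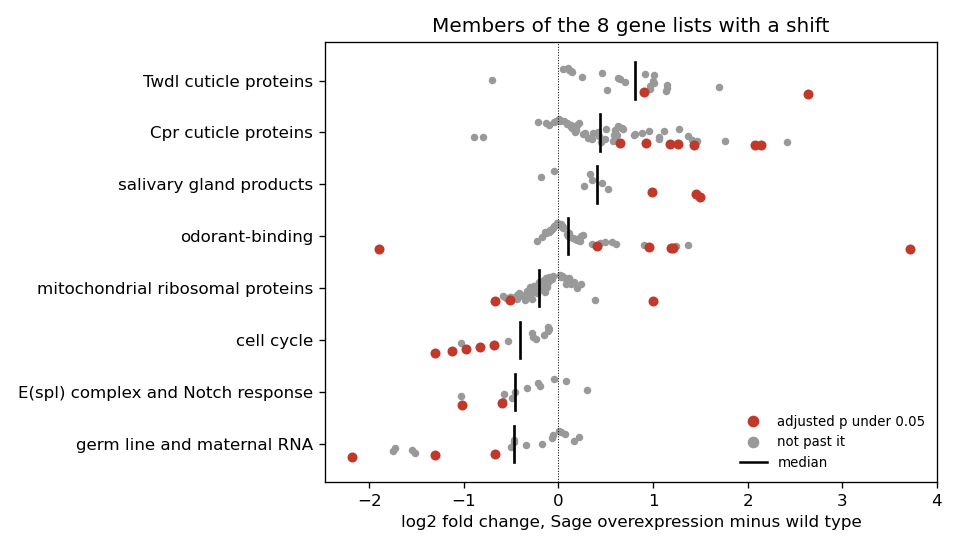
Log2 fold change (Sage overexpression minus wild type) of each measured member of the 8 gene lists that shifted, with members past an adjusted p of 0.05 in red and list medians as bars. Medians run from -0.47 for germ line and maternal RNA to 0.81 for the Tweedle family.

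Odorant-binding protein genes shifted upward, with 5 of 47 raised and 1 lowered, and 10 raised and 1 lowered when adjusted over the list alone (camera adjusted p 0.012; adjusted p = 0.781 with an estimated correlation). Obp46a rose from 4.34, within the range of the controls, to 8.05, Obp83cd rose 2.32-fold and Obp99b 2.29-fold, while Obp18a was 3.73-fold higher in wild type. The median was 0.10. Without wild type array 2, 11 rose, 1 rose without wild type array 1, and 2, 1 and 1 rose without Sage array 1, 2 and 3. Cytochrome P450 genes changed in both directions: of 82, 8 rose and 12 fell (12 and 16 adjusted over the list alone), with no shift as a list (camera adjusted p 0.58). Only 4 rose without wild type array 1 or any Sage array, and 7 and 5 fell without Sage arrays 1 and 3. Cyp6d2 rose 7.27-fold and Cyp4ae1 from 4.69 to 7.26, against the falls of Cyp6a8 and Cyp6a13. In the stress and xenobiotic list, 2 of 15 genes rose, the glutathione transferase genes GstD2 (6.63-fold) and GstD5 (3.17-fold), and 2 fell, Cyp6a8 and GstE3 (1.76-fold), with a camera adjusted p of 0.40. Adjusted over the list alone, 5 rose and 2 fell. Of 31 V-ATPase genes, which acidify secretory and endocytic compartments, 3 rose, led by Vha100-5 at 2.56-fold (camera adjusted p 0.22), 2 with the replicate block, and over the list alone 3 rose and 1 fell. Only 1 V-ATPase gene rose without wild type array 1 or any Sage array, and 2 without wild type array 3. Without Sage array 3, GstD5, GstE3, Obp83cd and Obp99b missed the threshold (adjusted p 0.085, 0.099, 0.137 and 0.109).

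Other tissue lists held few changes and no camera call in the planned fit, with camera adjusted p between 0.070 and 0.58 where a gene named here passed. Of 23 midgut and digestive genes, 3 rose, the sterol-binding genes Npc2e (15.7-fold) and Npc2d (from 4.59 to 6.15) and the trypsin gene alphaTry (2.21-fold), and Jon44E fell. In the crystal cell list 2 of 5 genes rose, the prophenoloxidase genes PPO2 (1.87-fold) and PPO1 (1.62-fold), and of 21 haemocyte and basement membrane genes Pxn rose 2.08-fold. Of 15 endocrine genes 3 rose, the prohormone convertase gene amon (2.20-fold), eclosion hormone (Eh, from 5.01 to 6.18) and corazonin (Crz, from 4.69 to 5.31). Npc2d and Eh in wild type, and Crz in both groups, lay within the range of the controls. The endocrine list did not pass (camera adjusted p 0.070), but passed with the replicate block (adjusted p 0.046) and without both arrays numbered 2 (adjusted p 0.044). In the glial list nrv2 fell 2.43-fold and alrm rose 1.44-fold, and in the heart list the potassium channel gene Ork1 fell from 5.59 to 4.10, within the range of the controls, and the GATA factor gene pnr 1.52-fold. None of 19 neuronal and none of 21 muscle genes passed limma's threshold over all genes or over the list alone. At an unadjusted p under 0.05, 2 genes of each list were higher and 0 lower. Their medians were 0.26 and 0.32, with camera adjusted p of 0.10 and 0.071, and both lists passed with the replicate block (adjusted p 0.011 for each), where 2 neuronal and 3 muscle genes rose and 0 fell. The muscle list also passed with median centring (adjusted p 0.039), and the neuronal list without both arrays numbered 2 (adjusted p 0.028). Among 6 measured of 17 listed heat shock genes, the co-chaperone gene stv rose 2.24-fold and Hsp68 fell 3.81-fold. Of 13 cell death genes the caspase genes Dcp-1 and Strica fell 1.68-fold and 1.59-fold. In the list of adult female and egg-chamber genes, Yp3, a yolk protein gene, rose from 5.32, within the range of the controls, to 6.85 and Vm26Aa 1.47-fold of 14 (camera adjusted p 0.22). Adjusted over the list alone, the genes that rose and fell numbered 3 and 2 for midgut, 2 and 1 for crystal cells, 1 and 0 for haemocytes, 4 and 1 for endocrine genes, 1 and 2 for glia, 1 and 3 for heart, 1 and 2 for heat shock, 0 and 3 for cell death, and 2 and 0 for adult female genes. Without Sage array 3, Npc2d, PPO1, Eh, Crz, nrv2, alrm, pnr, stv, Hsp68, Dcp-1, Strica and Vm26Aa missed the threshold (adjusted p from 0.055 for PPO1 to 0.182 for pnr), while Npc2e, alphaTry, PPO2, Pxn, amon, Ork1 and Yp3 passed whichever array was left out. None of 13 segmentation genes, 12 gap and dorsoventral genes, 12 JNK and wound response genes or 41 cytosolic ribosomal protein genes passed in limma over all genes or over the list alone. At an unadjusted p under 0.05 these lists held 0 higher and 3 lower, 0 and 2, 2 and 2, and 1 and 2 genes. With the replicate block 1 segmentation, 1 gap and dorsoventral and 1 JNK gene fell. The segmentation list had a camera adjusted p of 0.15 in the planned fit and shifted downward with array weights (adjusted p 0.0098), without wild type array 2 (adjusted p 0.0096) and without both arrays numbered 2 (adjusted p 0.014). The heart list did so with array weights (adjusted p 0.017) and without both arrays numbered 2 (adjusted p 0.045). Leaving out 1 array also brought calls for muscle, neurons, epidermis and cuticle formation, endocrine, heart, chitin metabolism and Osi genes, with lowest adjusted p of 0.0055, 0.012, 0.022, 0.027, 0.036, 0.039 and 0.047. Of 44 lists tested 8 shifted in camera, 0 with an estimated correlation and 12 with the replicate block. Fry called 6, of which 2, salivary gland products and cell cycle, were among the 8. The other 4 were larval glue genes, crystal cells and cell death (adjusted p 0.013 for each) and endocrine genes (adjusted p 0.011). At an unadjusted p under 0.05, camera called 14 lists, and 1 with an estimated correlation, the cell cycle list (p 0.024). The adjusted p of 0.781 is shared by many lists through the adjustment, and their unadjusted p differed. With an estimated correlation camera gave unadjusted p of 0.070 for gland products, 0.078 for Cpr and 0.14 for germ line genes. It gave 0.25 for odorant-binding, 0.28 for Enhancer of split, 0.31 for Tweedle and 0.60 for mitochondrial ribosomal genes.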

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

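Tests of the hybridisation controls, of the spread among gland products, of bright probe sets alone and of the 3′ control probe sets for rises of at least 4-fold were chosen after the results they bear on were seen. An Affymetrix control probe set outside the comparison, whose target the tables used here do not name, was higher on every Sage array than on every wild type array, at 6.08 ± 0.69 against 3.83 ± 0.06 (SD, n = 3), a log2 difference of 2.25. Of 120 control probe sets that are neither spike-ins, hybridisation controls nor named fly transcripts, 20 were higher on every Sage array, the other 19 by at most 0.52, and 1 was lower.

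The loss of polyA spike-in and 5′ signal on the Sage arrays goes with the group. A difference in hybridisation or scaling is argued against by the hybridisation controls, whose median log2 difference was 0.076. For the 446 lowered genes a 3′ bias of the labelled RNA cannot be told apart from a fall of the transcript, since 43 other probe sets of 34 of these genes had a median of -0.23 against -0.88 for the chosen ones; in the bright ones, above the median of all probe sets, 19 probe sets of 16 genes, it was -0.66 against -0.89. For the raised genes the preset rule fell on the side of a 3′ bias, with a median of 0.11 in 50 other probe sets of 44 genes against 0.88. Most of these probe sets are dim. The 14 bright ones had a median of 0.43 against 0.84, with 0.39 against 1.09 for the 4 of them whose genes rose at least 2-fold. For rises and falls alike, the position of a probe set along its transcript was not used. The chosen probe sets were the brightest of their gene and past the threshold, which by itself can leave smaller changes in the others. The comparison therefore cannot decide on a 3′ bias, and rises may partly reflect labelling. None of the 7 3′ control probe sets rose, the lowest and highest log2 changes among them being -0.59 and -0.046. These controls are all bright, whereas 46 of the 61 genes that rose at least 4-fold were in the lower 50% of wild type means. The controls therefore cannot show what labelling does to dim probe sets, and they do not decide on the 61 rises. A batch of labelling, for large and small changes alike, stays open and untested. So do the driver and transgene insertions carried in the Sage embryos alone.

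Higher cuticle genes (medians of 0.44 for Cpr, 0.81 for Tweedle, 0.13 for Osi and 0.27 for epidermis and cuticle formation) could come from Sage embryos that were older on average. That predicts lower early genes, and 1 of the 3 early lists had a median above 0, gap and dorsoventral genes at 0.02, against -0.25 for segmentation genes and -0.40 for cell cycle genes, and the segmentation list passed only in some settings (adjusted p 0.0098 with array weights). A value of 0.02 decides little, so a difference in age within stages 11 to 16 cannot be told apart from an effect of Sage on cuticle genes. Within the wild type group, array 2 differed from the mean of arrays 1 and 3 by medians of -1.09 for Tweedle, -0.56 for epidermis and cuticle formation, -0.26 for Cpr and -0.017 for Osi, so 3 of the 4 lists vary between arrays of one genotype.

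The rise of gland genes could come from more gland cells of the wild type kind, which would raise gland genes by a common factor. The 10 measured products ran from a log2 fold change of -0.18 for Papst2 to 1.497 for PH4alphaSG1, 5.11 standard errors of the difference apart, and 0 of them were lower by more than 2 of their standard errors. These genes were picked as the extremes of the 10. A standard error of the difference takes no account of that choice, so 5.11 is not a test of a common factor. Other tissues may express some of these genes, which would make unequal rises, and the larger rises of Eig71Ee and Sgs4 started near the floor, so added gland cells cannot be told apart from activation per cell. Activation of some gland genes by Sage in other cells is a candidate explanation, untested here because the RNA came from whole embryos.

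The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For changed probe sets and changed genes 1 of the 10 splits, the real one, gave as many, with 1149 and 969 against a highest count of 0 in the others. Each other split mixes wild type and Sage arrays on both sides, so any strong group difference widens the spread within its sides and lowers its count. Those counts of 0 therefore say little about chance. For shifted gene lists 8 of the 10 splits gave at least the real count of 8, with a highest count of 18, so the number of lists does not set the real split apart. For the salivary gland products 1 split gave a result as large, with -log10 p of 2.74 against a highest other of 1.81, and for the regulators 4 splits did, with 0.66 against 3.65. Of the 3 other splits that part all pairs of replicate numbers, the highest counts were 0 genes and 18 lists, and of the 6 that part 1 pair, 0 genes and 15 lists.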

How the results depend on the processing

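The setting without replicate number 2 in both groups was chosen after the data were seen. The log2 fold change of sage kept its direction and its call in every setting, from 4.37 to 4.71. The shift of the salivary gland products kept both in every setting but 1, from 0.49 to 0.61; with an estimated correlation the mean stayed 0.57 and the adjusted p was 0.78. Counts of probe sets and genes rose most with array weights (3986 probe sets, 3222 genes, 1621 up and 1601 down) and with the replicate block (2191 probe sets, 1767 genes, 881 up and 886 down), and fell by construction at an adjusted p of 0.01 (349 probe sets, 292 genes) and with treat (132 genes). No list shifted with an estimated correlation (0 of 44). Leaving out 1 array gave 335 to 1857 probe sets, 275 to 1638 genes, 199 to 850 rises, 76 to 788 falls and 7 to 13 lists. Of 87 named genes past the threshold 45, 41 and 37 lost it without Sage array 3, 2 and 1, 23 and 17 without wild type arrays 1 and 3, and 0 without wild type array 2, none with a change of sign. The paired fit with the replicate block ended the calls of dysf and Vha14-2 and added VAChT, sns, FASN1 and ImpL1, and among lists added neurons, muscle, endocrine genes and epidermis; it changed no other call of a named gene or list. Median centring put 48.7% and quantile normalization 58.2% of changed genes on the raised side, against 54.0%. Directions turned in results that passed no threshold. For fkh the log2 fold change was -0.0085 with median centring, -0.18 with array weights, -0.027 without number 2, and between -0.073 and 0.16 with 1 array left out. The direction that camera or fry gives a list rests on its genes together and can differ from the sign of the mean, which in the planned fit was 0.33 for the regulators, -0.014 for JNK, -0.14 for Jonah, -0.052 for amnioserosa and yolk and 0.028 for Gst. That direction, not always the mean, turned for the regulators with array weights (mean 0.15); for the JNK list with the dim probe sets left out (-0.060), trend and robust settings, the replicate block and fry (-0.014 in all 3), array weights (-0.014), and without number 2 (-0.069); for the Jonah proteases with median centring (-0.18), quantile normalization (-0.15), trend and robust settings, the replicate block and fry (-0.14 in all 3), array weights (-0.16) and without number 2 (-0.25); for the amnioserosa and yolk list with median centring (-0.090), quantile normalization (-0.034), the replicate block (-0.052) and without number 2 (-0.068); and for the Gst family with array weights (0.14). With 1 array left out it turned in the JNK (-0.053 to 0.027), Jonah (-0.19 to -0.052), amnioserosa (-0.15 to 0.032), gap (-0.16 to 0.00078), trachea (-0.24 to 0.023), neural precursor (-0.26 to -0.053) and haemocyte (0.027 to 0.28) lists. Except where a setting tests fewer arrays or a stricter threshold, the cause was not tested.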

Other observations

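Gene families by symbol stem, some of which overlap the fixed lists, were compared after the results were seen, as were the paragraphs that follow. Among 156 families, tested for rises and for falls (312 tests), 3 were over-represented by Fisher's exact test. In the yellow family, whose founding gene acts in cuticle pigmentation, 5 of 12 genes rose (adjusted p 0.015): yellow-d 15.2-fold, from 7.15 ± 0.52 to 11.08 ± 0.26, yellow-b 2.23-fold, yellow-e 2.03-fold, yellow-f2 1.79-fold and yellow-d2 1.69-fold. Of 9 genes with the stem Npc, 4 rose (adjusted p 0.039), all from the Npc2 group of sterol-binding proteins, Npc2e 15.7-fold, Npc2h 2.51-fold, and Npc2c and Npc2d from 4.57 to 7.85 and from 4.59 to 6.15, within the range of the control probe sets in wild type. Npc2d and Npc2e also stand in the fixed midgut list. Of 83 cytochrome P450 genes 12 fell (adjusted p 0.015), including Cyp6a8, Cyp6a13, Cyp309a2 (3.55-fold), Cyp6d5 (2.66-fold) and Cyp12c1 (2.53-fold), the same falls as in the fixed P450 list, which camera did not call. The carbonic anhydrases, with 4 of 13 raised, did not pass (adjusted p 0.15). Of these genes 2 yellow, 3 Npc2 and 5 P450 genes passed in each fit that left out 1 array.

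Raised genes lay next to each other on the chromosomes more often than random placement gave. Among 522 placed genes that rose, 46 adjacent pairs were found against a mean of 22.9 and a highest value of 42 in 10000 random placements (one-sided p 1e-04, the smallest they can give). The 445 placed genes that fell formed 30 pairs against a mean of 16.6 (p 0.001), and the 61 that rose at least 4-fold formed 2 against 0.313 (p 0.04). Neighbours that are members of one family were not separated from other neighbours.

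Probe sets of one gene disagreed in 2 genes for which a probe set not chosen changed at least 4-fold. For RFeSP, the Rieske iron-sulphur protein of respiratory complex III, one probe set rose from 4.57, within the range of the control probe sets, to 9.40 (adjusted p 8.1e-05), while the brighter one had a log2 fold change of -0.13 (adjusted p 0.70). For CG42335 one probe set fell from 6.27 to 4.11, within that range (adjusted p 6.8e-04), and the chosen one had a log2 fold change of 0.57 (adjusted p 0.040).

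The difference of replicate number 2 from numbers 1 and 3 was shared between the groups, with a Pearson correlation of 0.68 across 11983 genes, which are not independent replicates. Its correlation with the Sage effect, which rests on the same arrays, was -0.20 for the wild type difference and -0.04 for the Sage one. Wild type array 2 read lower than the mean of arrays 1 and 3 in neurons (median log2 difference -0.75), muscle (-0.69) and the Tweedle family (-1.09), and higher in mitochondrial ribosomal protein genes (0.60). Sage array 2 showed -0.40, -0.05, -0.22 and 0.18 in these lists.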
